A study of Mus musculus with 8 samples.

How the data were processed

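RNA was sequenced from tissue-resident (alveolar) macrophages sorted by flow cytometry from the lungs of C57BL/6 mice. KP cells, a mouse lung tumor line, had been injected into the tail vein of tumor-bearing mice, and lungs were taken at day 15 (d15) or day 35 (d35), per the labels. The growth protocol gives a harvest period that ends before the later day, and which is right was not resolved here. Naive mice carried no tumor. Per the labels' protocols, RNA came from 20000 sorted cells, 1 ng was made into cDNA with the SMART-Seq v4 low-input kit, and libraries were sequenced on an Illumina NextSeq instrument. The 8 libraries fell into 3 groups by their labels, with 3 naive, 2 d15 and 3 d35 libraries. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

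The submitters' processing notes name the aligner STAR 2.5, the genome build mm10 and edgeR without a version. The program and annotation used to count reads are not given in the sources used here, nor is whether counting used the strand. How reads shared by near-identical genes were assigned is therefore unknown, and values of major histocompatibility complex (MHC) class I heavy-chain genes and ribosomal protein genes, which have close copies, are uncertain in that respect. The deposited expression table holds 12701 genes in a scaled signal per gene that the authors made from read counts. Its values were tested against the form (reads + 0.5) divided by (library size + 1), scaled as CPM, and 100% of them came out as whole reads within 0.001, with a largest deviation of 5.1e-09. They are given below as scaled CPM. The gene with the fewest reads held 41 over all libraries, so the deposited table had already been filtered. The authors' deposited table of the d15 comparison holds log2 fold changes, a likelihood-ratio score and p-values, per the file headers. The d15 columns carry the numbers 2 and 3 while the sample titles carry 1 and 2. These columns were therefore assigned to the d15 group only, as replicate A (column number 2) and replicate B (column number 3).

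Because the deposited values are not raw counts, limma 3.58.1 (R 4.3.3) was used as the main test. It replaced the count test planned at the start, the quasi-likelihood test of edgeR. The limma test was run with an intensity trend on log2(value + 1), for 11273 genes with a value of at least 1 in at least 2 libraries. The group was the only term and all 8 libraries shared the spread estimate (residual df 5, prior df 5.72). The pseudocount and the filter were set once the unit was known. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05 in each of the 3 comparisons. The planned quasi-likelihood test of edgeR 4.0.16 was run on the recovered reads as an alternative. It called 383 genes at d15, 1737 at d35 and 820 between the times, of which 377, 1655 and 765 were also called by limma. At d15 it did not call Mmp12, Eci1, Elmo1 and Lrp1, 4 of the 33 limma calls under the naming rule given below. The limma step was tested on simulated counts for 11236 genes. For the d15 design it recovered 54.5% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 93.9% of those changed 4-fold, with 4.52% of its calls on unchanged genes. For the d35 design it recovered 48.5%, 79.4% and 95.5% at the same sizes, with 5.23% of its calls on unchanged genes. Genes were drawn independently, with the same dispersion of a gene in all groups. The simulated counts thus carry no variation shared across genes and no difference in spread between groups, and these rates may not hold for the real libraries.

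Design, gene lists, the naming rule and the first set of alternatives were fixed before the data were examined. Of 31 gene lists, 28 had at least 3 tested genes. They comprised 17 lists of macrophage states, lists of RNA-quality or dissociation genes and markers of other cell types. Sex-linked, eosinophil and erythrocyte lists had fewer tested genes and were not analysed here. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and limma's fry were run beside it. No list call held with an estimated correlation in any of the 3 comparisons. For most lists the count of changed members is given over all genes tested and adjusted over the list alone. The naming rule took, per comparison, the 6 largest rises and 6 largest falls past the adjusted p of 0.05 with a mean log2 value of at least 3, groups that did not overlap and a named gene. It also took the 2 members of each state list with the smallest adjusted p, the member with the highest mean of each quality or other-cell list, and the macrophage marker genes Siglecf, Itgax, Mertk and Cd68. Other list members and clock genes named in the text were chosen after their values were seen. Some genes are not reported here.

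Alternatives in the first set were size factors by relative log expression (RLE), no filter on low values, DESeq2 1.42.0 and limma-voom on recovered reads, the replicate number as a block, a fit of only the 2 groups compared, and leaving out each library. Added later were edgeR on recovered reads (the test first planned), pseudocounts of 0 and 3, a minimum value of 5, a block by the numbers of the column names and a correction for transcript length. Median transcript length came from the GENCODE M21 annotation of GRCm38 (mm10) and was available for 99.5% of tested genes. The length correction subtracted from each library the fitted trend of its deviations from the gene means on log2 length. The level of that trend was subtracted too, so the correction also re-centred each library. Gene coordinates are from the same annotation, with positions counted from 1.

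Recovered depth was 28525078, 38561195 and 27465745 reads in naive replicates 1 to 3. It was 30867016 and 32881507 reads in d15 replicates A and B, and 30756658, 33374738 and 39572173 reads in d35 replicates 1 to 3. At these depths 1 read corresponds to 0.0247 to 0.0353 scaled CPM, so values near or below that level rest on very few reads. Replicates of a group differed by more than counting noise, with chi-square per degree of freedom from 14.9 to 50.0, and none was treated as a repeat of another.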

Results

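The study profiled alveolar macrophages, the resident macrophages of the lung airspaces, from naive mice and from mice in which KP tumor cells had grown for 15 or 35 days by the sample labels, to follow how these cells change as tumors form. The growth protocol gives a harvest period that ends before the day of the d35 label, so the later time is uncertain. Expression was measured by RNA sequencing in 3 naive, 2 d15 and 3 d35 libraries. Between 12505 and 12644 of the genes in the table had at least 1 read in a library. Lysozyme (Lyz2) was the most abundant transcript in all 8 libraries, with 4.05% to 6.19% of the recovered reads, and the 10 most abundant genes took 10.7% to 15.6%. Pearson correlations of log2 values across genes within a group lay between 0.991 and 0.994 for naive, at 0.993 for d15 and between 0.988 and 0.989 for d35. Genes are not independent replicates. The first principal component held 53.1% of the variance and separated d35 libraries, at 36.6, 14.3 and 30.2, from naive libraries at -21.2, -18.6 and -18.3. The second component held 17.5% and set the d15 libraries, at -18.4 and -21.7, apart from the naive libraries at 8.40, 15.8 and 9.05. Replicate 2 of d35 lay closest to the other groups on the first component.

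**Figure D1:**
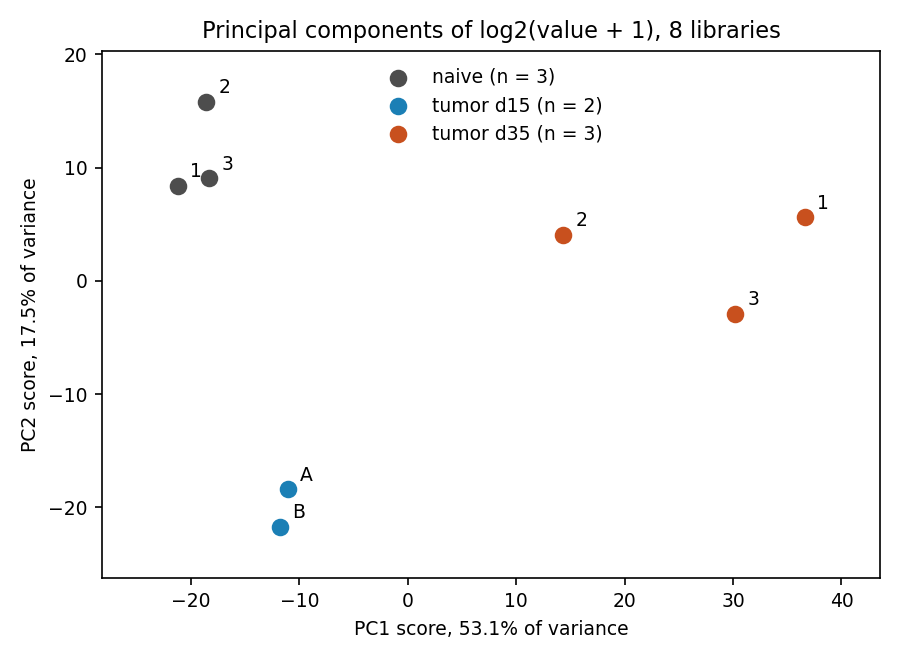
Scores of the 8 libraries on the first (x axis, 53.1% of variance) and second (y axis, 17.5%) principal components of log2 values, with points coloured by group. The d35 libraries lie at 14.3 or above on the first component and the d15 libraries at -18.4 or below on the second.

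At d15, genes of the circadian clock were among the 6 largest rises over naive macrophages, together with Fkbp5 and C1qb. This ranking is by the naming rule, which leaves out genes with a low mean. Nr1d1, which encodes the clock repressor REV-ERB alpha, was at 43.2 ± 0.02 scaled CPM at d15 (SD, n = 2) and 4.60 ± 0.87 in naive macrophages (SD, n = 3), a log2 fold change of 2.99 (limma adjusted p = 9.1e-06). Its paralog Nr1d2 reached 99.5 ± 6.3 against 17.1 ± 2.3 (adjusted p = 3.25e-06). Tef, a clock-controlled transcription factor, was at 66.8 ± 12.8 against 8.30 ± 0.37 (adjusted p = 3.25e-06). Fkbp5, a glucocorticoid receptor co-chaperone and target, rose from 85.0 ± 5.5 to 532 ± 209 (log2 fold change 2.58, adjusted p = 0.000246). The period gene Per2 rose from 19.5 ± 4.9 to 82.6 ± 35.8 (adjusted p = 0.00661). The complement subunit gene C1qb rose from 1.26 ± 0.71 to 7.29 ± 2.58 (adjusted p = 0.0439). Among genes that fell, the transporter gene Mfsd6 went from 33.2 ± 2.8 to 9.99 ± 0.98 (log2 fold change -1.64, adjusted p = 0.000867). The amino acid transporter gene Slc7a8 fell from 59.9 ± 0.9 to 27.4 ± 2.5 (adjusted p = 0.000246). Hivep3, Trp53i11, Ets1 and Nav2 fell by 1.47, 1.44, 1.21 and 1.09 on the log2 scale (adjusted p = 0.0231, 0.0241, 0.0224 and 0.0382). Nr1d1 lies on chromosome 11 at 98767932 to 98775333, Tef on chromosome 15 at 81802421 to 81826863 and Fkbp5 on chromosome 17 at 28399094 to 28517527. Nr1d2 lies on chromosome 14 at 18204054 to 18239127, Per2 on chromosome 1 at 91415982 to 91459324 and Mfsd6 on chromosome 1 at 52656286 to 52727462, all annotated as protein coding. In total 493 of 11273 genes changed (4.37%), 267 up and 226 down, of which 42 rose and 27 fell at least 2-fold. The count depended on single libraries, with 12 genes without d15 replicate B, 90 without d15 replicate A, 64 without naive replicate 2 and 110 without naive replicate 3. It was 232 without naive replicate 1, 1079 without d35 replicate 3, 316 by limma-voom and 333 after length correction. With DESeq2 it was 1455, and with only the naive and d15 libraries fitted 1179. Of 33 calls made by the naming rule, 6 held under every setting (Nr1d1, Nr1d2, Tef, Fkbp5, Mfsd6 and Slc7a8). Leaving out d15 replicate B ended 27 of the 33, with 24 lost without naive replicate 2, 22 without d15 replicate A, 21 without naive replicate 3, 16 without naive replicate 1 and 1 without d35 replicate 1.

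Some antigen presentation genes were higher at d15. H2-Aa and H2-Eb1, which encode MHC class II chains, rose from 299.5 ± 69.5 to 828 ± 100 and from 138 ± 31.4 to 381 ± 40.8 (adjusted p = 0.0268 and 0.032). Of 12 class II genes 5 rose (with H2-Ab1, Cd74 and H2-DMb2), none fell and 7 did not pass, and 9 rose when adjusted over the list alone. Class II camera adjusted p was 3.6e-05 (adjusted p = 0.741 with an estimated correlation). The class I list had 2 of 12 up, H2-K1 (813 ± 3.6 to 1083 ± 17.5, adjusted p = 0.0431) and the light chain B2m (1572 ± 153 to 2443 ± 54.7, adjusted p = 0.0437). Class I members numbered 3 when adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.771 with an estimated correlation). In the interferon gamma list 1 of 12 rose, the chemokine gene Cxcl9 (2.53 ± 0.59 to 10.3 ± 0.63), and 4 adjusted over the list alone. Its camera adjusted p was 0.0103 (adjusted p = 0.830 with an estimated correlation), while Gbp3 was at 23.8 against 10.4 (adjusted p = 0.0536). Nuclear oxidative phosphorylation genes rose in 3 of 22 cases, Cox6c (41.7 ± 2.1 to 60.8 ± 5.1), Atp5e (32.1 ± 2.1 to 46.6 ± 0.20) and Uqcrh, and in 15 adjusted over the list alone. These genes had a camera adjusted p of 6.6e-07 (adjusted p = 0.741 with an estimated correlation). Ribosomal protein genes rose in 8 of 22 cases and in all 22 adjusted over the list alone (camera adjusted p = 1.3e-11, and adjusted p = 0.741 with an estimated correlation). Their most abundant member Rpl4 was at 396 against 331 (adjusted p = 0.0800). Short transcripts as a class were higher at d15, with median log2 fold changes of 0.187 in the shortest and -0.147 in the longest of 5 equal length bins. Log2 length and log2 fold change correlated at r = -0.367 across 11217 genes, which are not independent replicates. In the apoptotic cell uptake list, Lrp1 and Elmo1 fell (adjusted p = 0.0476 and 0.0471), as did 4 of 14 adjusted over the list alone (camera adjusted p = 0.0329, and adjusted p = 0.741 with an estimated correlation). That list call was lost without d15 replicate A (adjusted p = 0.0691) and after length correction (0.0876). After length correction the calls of Cox6c, Atp5e, Uqcrh, H2-Ab1, Cd74, H2-DMb2, H2-K1, B2m, Lrp1 and Elmo1 ended, as did 6 of the 8 ribosomal calls and 13 of the 33 rule-named calls at d15. Over all 20 settings the log2 fold change of Lrp1 stayed between -0.436 and -0.364 (main -0.388). Those of Atp5e and Cox6c went down to 0.219 and 0.277 (main 0.528 and 0.532). Every member call named here was lost without d15 replicate B, where 33 of the 35 calls outside the naming rule ended. Of these 35, 30 were lost without naive replicate 2, 29 without naive replicate 3, 29 without d15 replicate A, 18 without naive replicate 1 and 4 without d35 replicate 1.

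Lists without a camera call at d15 still held changed members. Of 20 alveolar macrophage identity genes, Pparg, the transcription factor that maintains alveolar macrophages, rose from 331 ± 24.7 to 514 ± 36.9 (adjusted p = 0.00852). Atp6v0d2 rose from 2148 ± 71.8 to 3115 ± 83.4 (adjusted p = 0.0146) and Ear2 by 0.55 on the log2 scale, while the lipase gene Lpl fell from 3853 ± 590 to 2267 ± 480 (adjusted p = 0.0266). Adjusted over the list alone, 8 rose and 4 fell (camera adjusted p = 0.321). Among immune regulation genes the chemokine gene Ccl17 rose from 0.78 ± 0.34 to 6.42 ± 2.60 (adjusted p = 0.0133) and Il4ra by 0.51. Cd274, which encodes PD-L1, fell from 341 ± 25.1 to 212 ± 48.8 (adjusted p = 0.0191) as did Lilrb4a, by 0.61 on the log2 scale. Of the 16, 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.350). In lipid handling the desaturase gene Scd2 fell from 64.3 ± 7.4 to 35.2 ± 0.01 (adjusted p = 0.00278) and the cholesterol exporter Abca1 from 131 ± 22.5 to 72.0 ± 0.52 (adjusted p = 0.00692), with Lpl and Npc1 also lower and Dgat2 higher. Adjusted over the list alone 3 of 20 rose and 6 fell, and the list median of 0.05 and mean of -0.057 differed in sign (camera adjusted p = 0.344, direction down). The metalloelastase gene Mmp12 rose from 25 ± 8.3 to 73.5 ± 9.3 (adjusted p = 0.0427), the only matrix gene of 21 to pass, with 2 adjusted over the list alone (camera adjusted p = 0.549). The Mmp14 level was at 7.69 against 1.94 (adjusted p = 0.0559). Single members rose in the type I interferon (Ifih1), fatty acid oxidation (Eci1) and glycolysis and hypoxia (Bnip3) lists, and Txnrd1 fell in the oxidative stress list, with camera adjusted p = 0.644, 0.0668, 0.344 and 0.496. Adjusted over the list alone, 4 of 16 fatty acid oxidation genes rose and the other 3 lists kept 1 member each. No member passed the limma test in the NF-kB, growth factor, cholesterol biosynthesis or cell cycle lists (camera adjusted p = 0.788, 0.131, 0.0940 and 0.321). The Il1b level was at 28.5 ± 12.1 against 69.7 ± 33.6 (adjusted p = 0.148). The macrophage marker genes Siglecf (574 ± 22.6 against 719 ± 36.6), Itgax (777 against 841), Mertk (443 against 472) and Cd68 (1078 against 964) did not pass, with adjusted p = 0.0569, 0.435, 0.561 and 0.303. The calls of Ear2, Npc1, Mmp12, Eci1, Bnip3 and Txnrd1 ended after length correction. Over all 20 settings the log2 fold change of Mmp12 stayed at 1.36 or above (main 1.56), while that of Eci1 went down to 0.213 (main 0.369). All calls in this group of lists ended without d15 replicate B, among 27 of 33 rule-named and 33 of 35 other calls lost there. Leaving out naive replicate 2 ended 24 and 30 of these and naive replicate 3 ended 21 and 29. Without d15 replicate A 22 and 29 were lost, without naive replicate 1 16 and 18, and without d35 replicate 1 1 and 4.

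Most markers of other cell types fell or did not pass at d15. Endothelial markers fell in 3 of 13 cases, Calcrl (171 ± 5.1 to 116 ± 6.3), Kdr and Vwf, also 3 adjusted over the list alone. Endothelial camera adjusted p was 0.00322 (adjusted p = 0.741 with an estimated correlation). Their sum was 317 ± 38.2 scaled CPM in naive and 215 ± 27.5 in d15 libraries, and the list call was lost without d15 replicate A (adjusted p = 0.121). B cell markers fell in 1 of 6 cases and in 4 adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.741 with an estimated correlation). Fibroblast markers fell in 1 of 9 cases, the collagen gene Col3a1 (8.49 ± 2.72 to 1.76 ± 0.58), and in 1 adjusted over the list alone (camera adjusted p = 0.00322, and adjusted p = 0.741 with an estimated correlation). Of 19 monocyte and interstitial macrophage markers C1qb rose and Cx3cr1 was among those that fell, with 2 up and 3 down adjusted over the list alone. The median of -0.081 and mean of 0.032 of that list differed in sign (camera adjusted p = 0.549, direction down). Clec9a alone among 6 dendritic cell markers changed and fell, with a list median of 0.0021 and a mean of -0.033 (camera adjusted p = 0.712, direction down). No neutrophil, T and NK cell or epithelial and tumor marker passed the limma test (camera adjusted p = 0.601, 0.300 and 0.549). Immediate-early and heat-shock genes, which mark tissue dissociation and stress, rose in 3 of 23 cases (Ier3, Dnaja1 and Hsph1) and in 5 adjusted over the list alone. Their camera adjusted p was 0.0425 (adjusted p = 0.830 with an estimated correlation). Their sum was 5639 in naive replicate 1 against 10910 and 10340 in the other naive libraries and 9376 and 11110 at d15. The list call was lost without naive replicate 1 (adjusted p = 0.340) and without d15 replicate B (adjusted p = 0.103). Mitochondrially encoded mRNAs had no changed member by limma (camera adjusted p = 0.0544). The single-gene calls of Calcrl, Kdr, C1qb, Ier3 and Hsph1 ended after length correction. Over all 20 settings the log2 fold change of Calcrl stayed between -0.610 and -0.458 (main -0.555) and that of C1qb between 1.26 and 2.71 (main 1.89). Every single-gene call of this group ended without d15 replicate B, where 33 of 35 calls outside the rule were lost. Most also ended without naive replicate 2 (30), naive replicate 3 (29) or d15 replicate A (29), and 18 and 4 of the 35 without naive replicate 1 and d35 replicate 1.

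**Figure D2:**
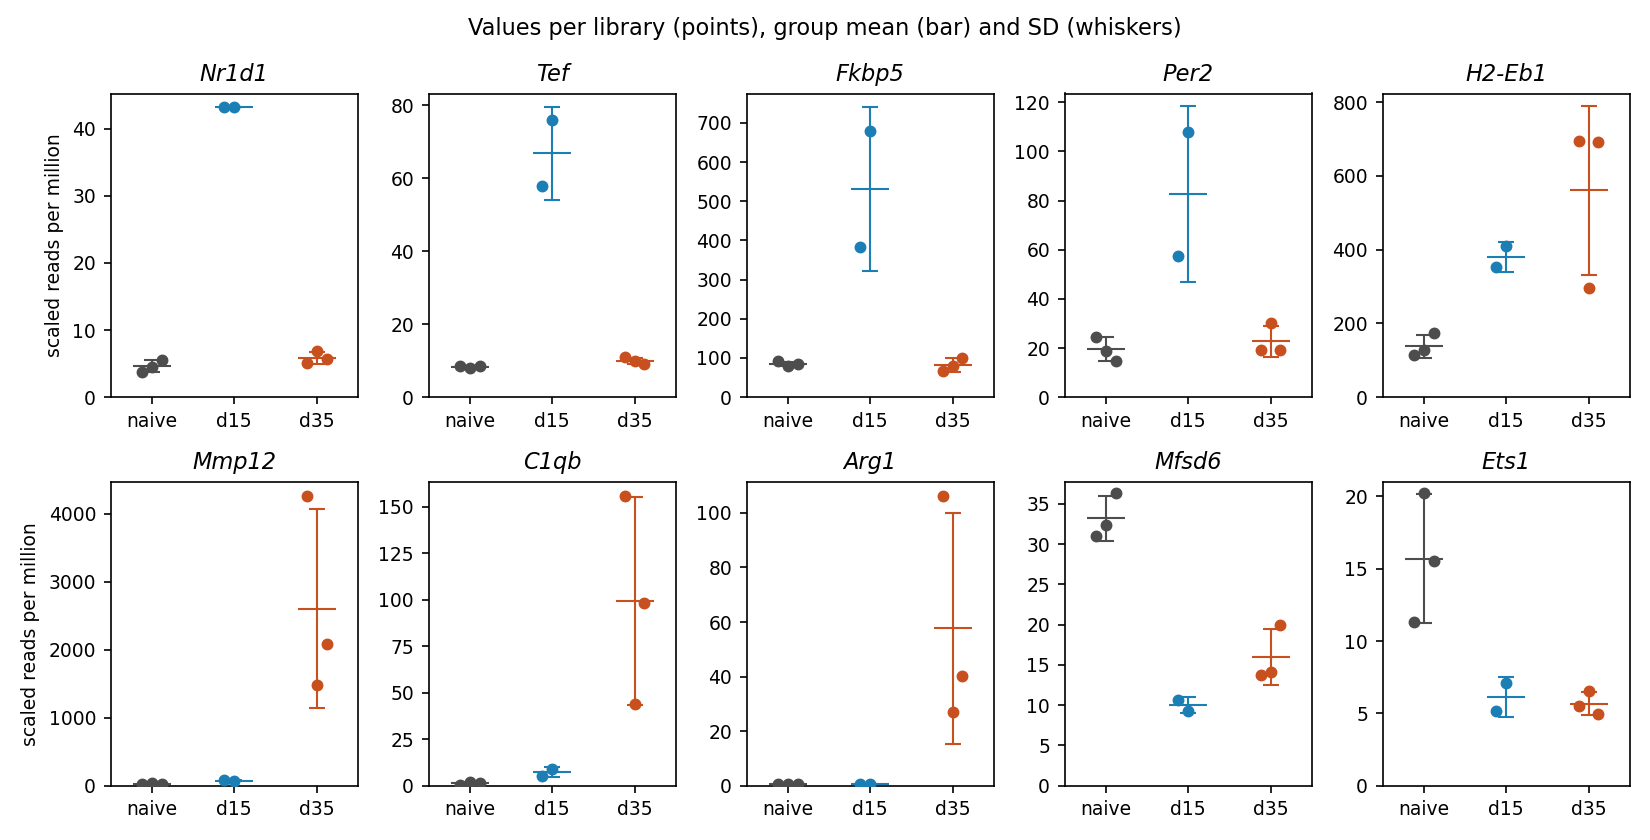
Scaled CPM (y axes) of 10 genes in naive, d15 and d35 macrophages, with a point per library, a bar at the group mean and whiskers of 1 SD (n = 3, 2 and 3). Nr1d1, Tef, Fkbp5 and Per2 lie highest at d15, and Mmp12, C1qb and Arg1 at d35.

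At d35, the largest rises over naive macrophages included Mmp12, C1qb, Ccl17 and Arg1. Mmp12, a macrophage metalloelastase, went from 25 ± 8.3 to 2608 ± 1462 scaled CPM (SD, n = 3 in each group), a log2 fold change of 6.55 (limma adjusted p = 7.5e-06). C1qb, a member of the monocyte and interstitial macrophage marker list, reached 99.3 ± 56.0 from 1.26 ± 0.71 (log2 fold change 5.35, adjusted p = 4.34e-05). Ccl17, which encodes a chemokine for CCR4-bearing T cells, reached 72.2 ± 29.6 from 0.78 ± 0.34 (adjusted p = 8.59e-06). Arg1, the arginine-degrading enzyme arginase, rose from 0.70 ± 0.02 to 57.8 ± 42.3 (log2 fold change 4.88, adjusted p = 5.12e-05). Large rises were also seen for Pla2g7, a lipoprotein-associated phospholipase (2.21 ± 0.43 to 76.5 ± 50.4), and the membrane metalloprotease gene Mmp14 (1.94 ± 1.00 to 63.7 ± 33.3), with adjusted p = 6.18e-05 and 0.000103. The chaperone gene Clu (2.64 ± 0.43 to 79.1 ± 46.5) and Fam20c (6.29 ± 4.50 to 121 ± 61.5) rose with adjusted p = 0.000287 and 0.00042. Falls were smaller, with Ets1 (15.7 ± 4.5 to 5.67 ± 0.80, adjusted p = 0.00327), Nav2 (100.4 ± 20.5 to 42.3 ± 16.6, adjusted p = 0.00553) and Adgrf5 (33.0 ± 10.0 to 11.5 ± 2.5, adjusted p = 0.0087) lower under every setting. Dnah11 fell from 16.8 ± 1.32 to 5.85 ± 3.01, Itgad from 31.2 ± 5.12 to 13.1 ± 9.11 and Ptprb from 23.2 ± 9.02 to 8.58 ± 3.05 (adjusted p = 0.0194, 0.0282 and 0.0235). Mmp12 lies on chromosome 9 at 7344381 to 7369499 with 11 annotated exons in its longest form, C1qb on chromosome 4 at 136880129 to 136886187 and Ccl17 on chromosome 8 at 94810453 to 94812036. Arg1 lies on chromosome 10 at 24915221 to 24927484, Pla2g7 on chromosome 17 at 43568098 to 43612201, Mmp14 on chromosome 14 at 54431612 to 54445364 and Clu on chromosome 14 at 65968483 to 65981547, all protein coding. Of 11273 genes 1824 changed (16.2%), 1112 up and 712 down, of which 270 rose and 57 fell at least 2-fold. The count was 900 without naive replicate 1, 635 without naive replicate 2, 967 without naive replicate 3, 1035 without d35 replicate 1 and 995 without d35 replicate 3. Length correction gave 1258 genes, 1063 of them among the 1824, and the share of rises went from 61.0% to 52.5%. It also re-centred each library, and the median log2 fold change of all genes moved from -0.00223 to -0.0345. The lower share of rises therefore cannot be put down to length alone. Under every setting 35 of 51 rule-named calls held. Of the 51, 11 were lost without naive replicate 2, 9 without naive replicate 3, 9 without d35 replicate 1, 6 without naive replicate 1 and 6 without d35 replicate 3. Leaving out d15 replicate A or B ended 3 each and d35 replicate 2 ended 1, and the lost calls included Dnah11, Itgad and Ptprb.

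Matrix and remodelling genes rose in 13 of 21 cases at d35 and none fell, with 16 up and 1 down adjusted over the list alone (camera adjusted p = 5.4e-09, and adjusted p = 0.335 with an estimated correlation). Besides Mmp12 and Mmp14 they included the protease gene Adam8 (0.28 ± 0.05 to 32.9 ± 25.4, adjusted p = 8.54e-05), osteopontin (Spp1, 776 ± 101 to 2406 ± 543) and the collagen-degrading cathepsin K (Ctsk, 545 ± 81.6 to 1351 ± 322). Immune regulation genes rose in 6 of 16 cases, with 7 up and 1 down adjusted over the list alone (camera adjusted p = 0.00196, and adjusted p = 0.387 with an estimated correlation). Among them were Arg1, Ccl17, the lipid receptor Trem2 (33.7 ± 2.55 to 69.5 ± 21.6) and Gpnmb (592 ± 39.8 to 853 ± 103). Interferon gamma response genes rose in 11 of 12 cases and in all 12 adjusted over the list alone (camera adjusted p = 5.4e-09, and adjusted p = 0.335 with an estimated correlation). Examples were the GTPase gene Gbp2 (38.9 ± 2.2 to 104 ± 26.0, adjusted p = 0.00061) and Cxcl9 (2.53 ± 0.59 to 26.2 ± 14.0, adjusted p = 0.000875). MHC class I genes rose in 9 of 12 cases and 10 adjusted over the list alone (camera adjusted p = 2.8e-08, and adjusted p = 0.335 with an estimated correlation). They included H2-K1 (813 ± 3.6 to 1465 ± 164) and the peptide transporter Tap1 (45.5 ± 2.8 to 77.8 ± 11.3). MHC class II genes rose in 8 of 12 cases, also 8 adjusted over the list alone (camera adjusted p = 6.8e-06, and adjusted p = 0.387 with an estimated correlation). Among them, H2-Eb1 rose from 138 ± 31.4 to 561 ± 228 and H2-DMb1 from 155 ± 13.7 to 295 ± 68.4. Type I interferon genes rose in 7 of 18 cases and 8 adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.468 with an estimated correlation). These were led by Zbp1 and the oligoadenylate synthetase Oas1a (19.3 ± 3.3 to 36.6 ± 7.1), and 4 of the 7 calls ended after length correction.

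Members of metabolic and stress lists rose as well at d35. Glycolysis and hypoxia genes rose in 11 of 20 cases and 12 adjusted over the list alone (camera adjusted p = 2.6e-05, and adjusted p = 0.387 with an estimated correlation). They included Pgam1 (35.3 ± 0.5 to 60.9 ± 7.9) and Tpi1, whose call ended after length correction. Oxidative phosphorylation genes rose in 14 of 22 cases and 15 adjusted over the list alone (camera adjusted p = 2.8e-08, and adjusted p = 0.387 with an estimated correlation). Of these 14 calls 11 ended after length correction, among them Uqcrh and Atp5e (log2 fold change 0.58 and 0.59). Ribosomal protein genes rose in 5 of 22 cases (Rpl7, Rpl18, Rpl19, Rps2 and Rps14) and in 18 adjusted over the list alone (camera adjusted p = 3.3e-07, and adjusted p = 0.543 with an estimated correlation). None of the 5 calls held after length correction or without naive replicate 1 or 2. Length and log2 fold change correlated at -0.283 across 11217 genes, which are not independent replicates. Medians were 0.198 in the shortest and -0.152 in the longest of 5 length bins. Oxidative stress genes rose in 7 of 13 cases and 9 adjusted over the list alone (camera adjusted p = 3.2e-05, and adjusted p = 0.254 with an estimated correlation). They included the heme oxygenase gene Hmox1 (131 ± 7.4 to 203 ± 22.6) and Prdx1. In the cholesterol biosynthesis list 5 of 20 rose (including Mvd, Dhcr7, Pmvk and Sc5d) and 8 adjusted over the list alone (camera adjusted p = 0.000579, and adjusted p = 0.653 with an estimated correlation). Mvd held in every leave-one-out set, and the calls of Dhcr7, Pmvk and Sc5d ended without naive replicate 2, naive replicate 3 or d35 replicate 1. Cell cycle genes fell in 7 of 31 cases, including the replication helicase gene Mcm7 (62.1 ± 1.3 to 45.2 ± 5.0), Mcm2, Mcm4, Mcm6, Top2a, Rrm2 and Foxm1. The mitotic cyclin gene Ccnb2 rose from 40.8 ± 2.1 to 68.5 ± 8.7 (adjusted p = 0.00407). Adjusted over the list alone 8 fell and 1 rose (camera adjusted p = 0.0162, and adjusted p = 0.692 with an estimated correlation). The call was lost without d35 replicate 3 (adjusted p = 0.173), and all of the 7 falls ended without naive replicate 2.

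Lists without a camera call at d35 included the growth factors, of which 5 of 12 rose (Inhba, Igf1, Csf1, Pdgfa and Hbegf) and Pdgfc fell, the same counts when adjusted over the list alone (camera adjusted p = 0.143). Inhba, the activin A subunit, rose from 0.67 ± 0.33 to 13.7 ± 7.8 (adjusted p = 0.000496) and Igf1 from 26.2 ± 4.2 to 83.0 ± 33.8 (adjusted p = 0.00293). In lipid handling 5 of 20 rose, the scavenger receptor Msr1 (27.1 ± 4.7 to 141 ± 66.2, adjusted p = 0.0011), Npc2, Lipa, Fabp5 and Apoe. Abca1 and Cidec fell, with 5 up and 3 down adjusted over the list alone (camera adjusted p = 0.316). Of 14 apoptotic uptake genes Mfge8, which bridges dying cells to phagocytes, rose from 20.4 ± 1.3 to 142 ± 98.1 (adjusted p = 0.0022) with Cd300lb, and Lrp1 and Elmo1 fell. In that list 3 rose and 4 fell when adjusted over the list alone, and its median of -0.026 and mean of 0.169 differed in sign (camera adjusted p = 0.668). Alveolar identity genes went both ways, with Car4 (586 ± 129 to 908 ± 95, adjusted p = 0.0224) and Ear2 up and Siglecf (719 ± 36.6 to 591 ± 47.1, adjusted p = 0.033), Bhlhe41 and Cidec down. Of these 20 genes 4 were up and 4 down adjusted over the list alone (camera adjusted p = 0.316). NF-kB targets had Ccl4 up (1.67 ± 0.10 to 9.0 ± 3.63) and Nlrp3 down, and fatty acid oxidation genes had Acaa2 up and Cpt1a down (camera adjusted p = 0.209 and 0.668). Of 16 NF-kB targets 1 rose adjusted over the list alone, and of 16 fatty acid oxidation genes 3 rose and 1 fell. Cd68, a macrophage lysosomal protein, rose from 964 ± 101 to 1400 ± 47.6 (adjusted p = 0.00383). Itgax (902 ± 77.1 against 841 ± 9.83) and Mertk (462 ± 42.9 against 472 ± 19.8) did not pass (adjusted p = 0.422 and 0.796). In this group Inhba, Igf1, Csf1, Msr1, Npc2, Mfge8, Elmo1, Ccl4 and Cd68 held under every setting, and Fabp5 was lost only after length correction. The other calls were lost in at least 1 leave-one-out set, that of Siglecf in 7 of them. Of the 127 calls outside the naming rule, 69 were lost without naive replicate 2, 48 without naive replicate 3, 47 without d35 replicate 3 and 45 without naive replicate 1. A further tally gave 42 without d35 replicate 1, 20 without d15 replicate B, 19 without d15 replicate A and 9 without d35 replicate 2.

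Other-cell markers moved in opposite directions at d35. Monocyte and interstitial macrophage markers rose in 8 of 19 cases and fell in 1. The rises included C1qb, C1qa (1.03 ± 0.50 to 40.3 ± 25.4), C1qc and Itgam (1.99 ± 0.11 to 8.34 ± 3.33). Adjusted over the list alone 8 were up and 3 down (camera adjusted p = 0.0401, and adjusted p = 0.676 with an estimated correlation). Their sum was 589 ± 135 in naive and 892 ± 174 in d35 libraries. The list call was lost without naive replicate 1 (adjusted p = 0.134), without d35 replicate 1 (0.0539), without d35 replicate 3 (0.0534) and with the replicate block (0.0601). Among 16 epithelial and tumor markers the keratin genes Krt8 (0.26 ± 0.13 to 15.0 ± 4.4) and Krt18 (0.21 ± 0.11 to 14.6 ± 6.4) and Hopx rose. Epcam fell from 201 ± 15.5 to 120 ± 41.9, with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.292). Endothelial markers fell in 8 of 13 cases and 10 adjusted over the list alone (camera adjusted p = 1.2e-06, and adjusted p = 0.335 with an estimated correlation). They included Calcrl (171 ± 5.1 to 112 ± 20.3). B cell markers fell in 3 of 6 cases (including Cd79b and Cd79a) and 5 adjusted over the list alone (camera adjusted p = 0.00167, and adjusted p = 0.335 with an estimated correlation). Fibroblast markers fell in 2 of 9 cases, Col3a1 and Inmt, also 2 adjusted over the list alone (camera adjusted p = 0.0212, and adjusted p = 0.653 with an estimated correlation). That call was lost without naive replicate 2 (0.0945), without naive replicate 3 (0.128) and without d35 replicate 1 (0.0620). The interleukin 7 receptor gene Il7r rose from 1.13 ± 0.48 to 15.6 ± 12.8 (adjusted p = 0.00363) as 1 of 5 T and NK cell markers. The median of -0.139 and mean of 0.577 of that list differed in sign (camera adjusted p = 0.566). Neutrophil and dendritic cell lists had 2 (S100a9 and Ltf) and no changed members by limma (camera adjusted p = 0.193 and 0.788). Of 6 neutrophil markers 3 rose and 1 fell adjusted over the list alone. Immediate-early and heat-shock genes went both ways, with Ier3, Dnaja1 and Hspe1 up and Jun and Btg2 down (camera adjusted p = 0.668). The list sum was 4139 in d35 replicate 1 against 6264 and 9202 in the other d35 libraries. Mitochondrially encoded mRNAs had no changed member (camera adjusted p = 0.962). The calls of C1qb, C1qa, C1qc, Itgam, Krt8, Krt18, Hopx, Calcrl, Cd79b, Dnaja1 and Il7r held in every leave-one-out set. Calls of Epcam, Inmt, Col3a1, Jun and Btg2 were lost without naive replicate 2, naive replicate 3 or d35 replicate 1, which ended 11, 9 and 9 of the 51 rule-named calls. Ier3 was lost without naive replicate 2, and Cd79a, Hspe1, S100a9 and Ltf without any naive replicate or without d35 replicate 1.

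**Figure D3:**
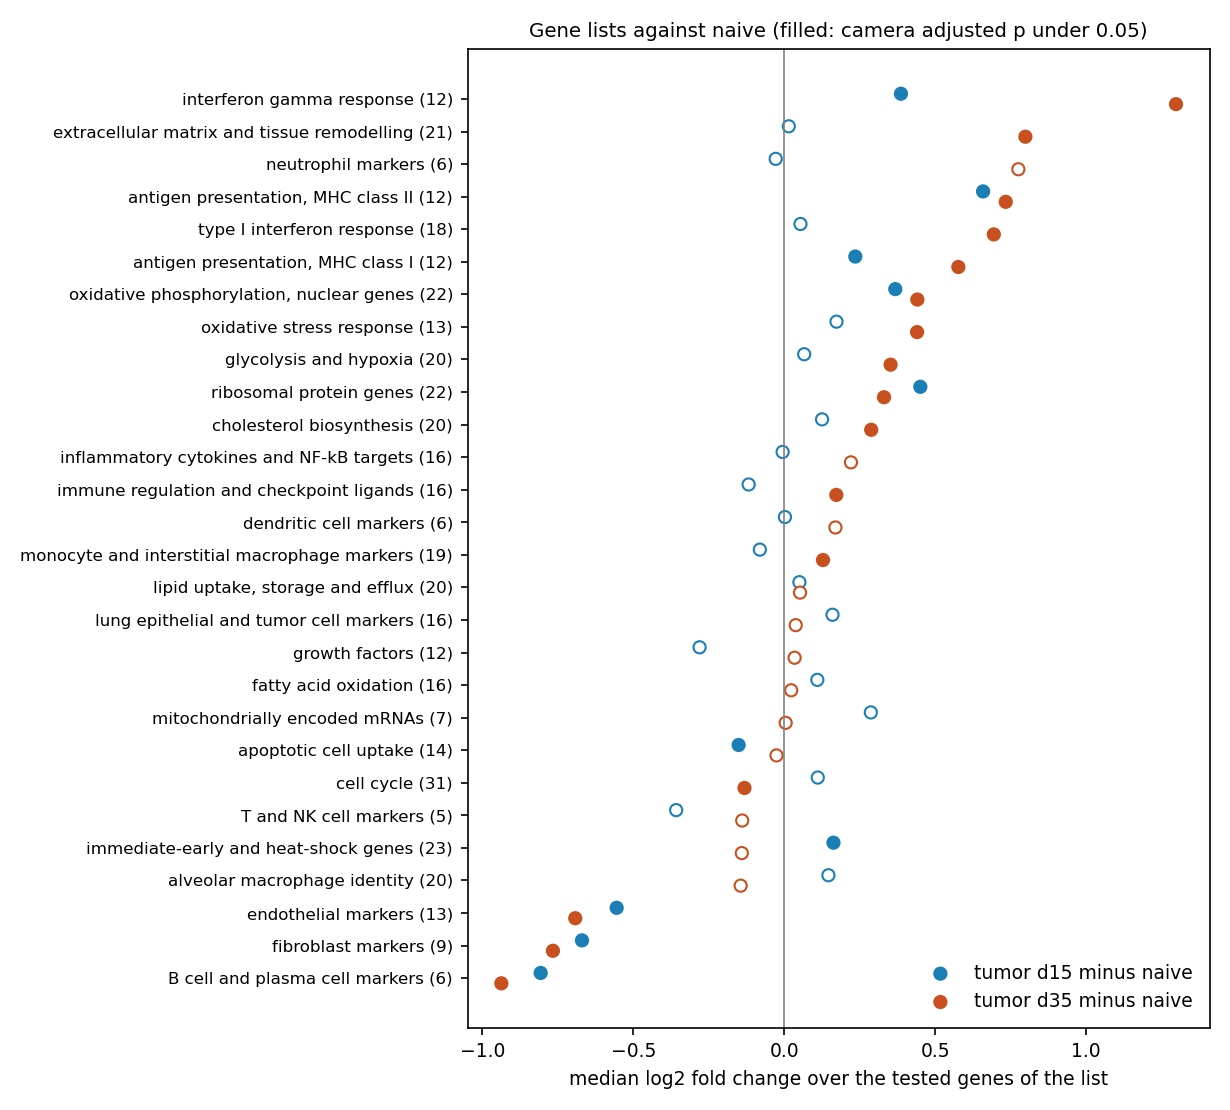
Median log2 fold change over naive (x axis) of the members of each gene list (y axis) at d15 and d35. Filled points passed camera at an adjusted p under 0.05, 10 lists at d15 and 16 at d35; no list passed with an estimated correlation.

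Set directly against d15, d35 macrophages were higher in Mmp12, Fam20c and Clu and lower in Nr1d1, Fkbp5 and Tef. Mmp12 rose from 73.5 ± 9.3 (SD, n = 2) to 2608 ± 1462 (SD, n = 3), a log2 fold change of 4.99 (limma adjusted p = 4.73e-05). Fam20c rose from 4.95 ± 2.90 to 121 ± 61.5, Clu from 2.81 ± 0.03 to 79.1 ± 46.5, Pla2g7 from 3.49 ± 1.00 to 76.5 ± 50.4 and C1qb from 7.29 ± 2.58 to 99.3 ± 56.0. Sema4d, a semaphorin on immune cells, rose from 3.86 ± 0.18 to 43.5 ± 19.3 (adjusted p = 0.000239). Nr1d1 fell from 43.2 ± 0.02 to 5.84 ± 0.91 (log2 fold change -2.70, adjusted p = 1.7e-05), Tef from 66.8 ± 12.8 to 9.98 ± 0.84 and Nr1d2 from 99.5 ± 6.3 to 22.2 ± 1.2. Fkbp5 fell from 532 ± 209 to 82.1 ± 17.6 (adjusted p = 0.000101) and Per2 from 82.6 ± 35.8 to 22.8 ± 6.3. The tight junction gene Cldn1 fell from 145 ± 0.4 to 42.6 ± 6.2 (adjusted p = 0.00176). Sema4d lies on chromosome 13 at 51685529 to 51793747 and Cldn1 on chromosome 16 at 26356642 to 26371841, both protein coding. In total 833 genes differed (7.39%), 517 higher and 316 lower at d35, against 513 higher and 503 lower after length correction. Between the times, length and log2 fold change correlated at only -0.033. The correction also re-centred each library, and the median log2 fold change of all genes moved from -0.00256 to -0.0395. The more even split therefore cannot be put down to length alone. The count was 193 without d15 replicate B, 312 without d15 replicate A, and 421 with only these 2 groups fitted. Of 39 rule-named calls 19 held under every setting, 13 were lost without d15 replicate B and 11 without d15 replicate A. All genes named above held in every leave-one-out set except Per2, lost without d15 replicate B. By limma-voom 7 of the 39 calls were lost, that of Clu among them (adjusted p = 0.0598).

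Matrix genes were higher at d35 than at d15 in 11 of 21 cases, with 16 up and 1 down adjusted over the list alone (camera adjusted p = 2.3e-10, and adjusted p = 0.358 with an estimated correlation). Immune regulation genes were higher in 7 of 16 cases and Havcr2 was lower, with 10 and 1 adjusted over the list alone (camera adjusted p = 7.6e-06, and adjusted p = 0.358 with an estimated correlation). Arg1 rose from 0.55 ± 0.03 to 57.8 ± 42.3 (log2 fold change 5.01, adjusted p = 0.000101), and Ccl17 and Adam8 by 3.26 and 3.77. Growth factor genes rose in 3 of 12 cases (Inhba, Csf1 and Igf1) and 4 adjusted over the list alone (camera adjusted p = 0.000858, and adjusted p = 0.358 with an estimated correlation). MHC class I genes rose in 4 of 12 cases (Tap1, H2-K1, H2-T23 and Nlrc5) and 8 adjusted over the list alone (camera adjusted p = 1.4e-05, and adjusted p = 0.358 with an estimated correlation). Interferon gamma genes rose in 3 of 12 cases, Iigp1 (2.33 ± 0.10 to 14.2 ± 7.8), Gbp2 and Ido1, which had 1 read at d15, and 9 adjusted over the list alone. Their camera adjusted p was 4.5e-06, and adjusted p = 0.358 with an estimated correlation. In the type I interferon list Usp18 rose, with 6 up and 1 down of 18 adjusted over the list alone (camera adjusted p = 4.7e-05, and adjusted p = 0.460 with an estimated correlation). Oxidative stress genes rose in 5 of 13 cases, the cystine transporter gene Slc7a11 (7.74 ± 1.60 to 30.0 ± 12.5), Txnrd1, Srxn1, Hmox1 and Prdx1, and 8 adjusted over the list alone. For them the camera adjusted p was 4.7e-05 (adjusted p = 0.243 with an estimated correlation). Glycolysis genes rose in 6 of 20 cases, including the lactate exporter Slc16a3 (54.5 ± 3.1 to 96.1 ± 10.6), and Bnip3 fell. Adjusted over the list alone 10 were up and 2 down (camera adjusted p = 0.000157, and adjusted p = 0.358 with an estimated correlation). Lipid genes rose in 6 of 20 cases and fell in 2, with Scd2 up from 35.2 ± 0.01 to 71.9 ± 3.2 and the lipid droplet gene Cidec down from 654 ± 38.8 to 371 ± 33.0 together with Dgat2. In this list 9 were up and 2 down adjusted over the list alone (camera adjusted p = 0.00632, and adjusted p = 0.358 with an estimated correlation). Alveolar identity genes fell in 4 of 20 cases, Pparg (514 ± 36.9 to 308 ± 27.6, adjusted p = 0.00163), Cidec, Fabp1 and Atp6v0d2. Lpl rose, with 5 down and 1 up adjusted over the list alone (camera adjusted p = 0.0331, and adjusted p = 0.544 with an estimated correlation). That call was lost without d15 replicate A (0.0615), d35 replicate 1 (0.0613) or d35 replicate 3 (0.183) and with the replicate block (0.0525). Cell cycle genes fell in 8 of 31 cases, among them Mcm6 and Mcm7, and Ccnb2 rose. With 12 down and 1 up adjusted over the list alone, the camera adjusted p was 0.000455 (adjusted p = 0.544 with an estimated correlation), a call lost without d15 replicate A (0.170). Arg1, Ccl17, Adam8, Inhba, Slc16a3, Scd2, Cidec and Pparg held in every leave-one-out set, as did Ido1. By limma-voom the calls of Arg1 (adjusted p = 0.0893), Adam8 (0.0714), Inhba (0.0533), Csf1, Iigp1, Gbp2, H2-T23, Hmox1 and Havcr2 were lost. Csf1, Igf1, Lpl, Txnrd1, Bnip3 and Ccnb2 were lost without d15 replicate B, Slc7a11, Mcm6 and Mcm7 without d15 replicate A, and Tap1, Usp18, Srxn1, Dgat2 and Atp6v0d2 without either. Iigp1, Fabp1 and H2-K1 were lost without either or without d35 replicate 1, and H2-T23, Nlrc5, Gbp2, Hmox1, Prdx1 and Havcr2 also without naive replicate 2.

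Other-cell and quality lists differed between the times too. Monocyte and interstitial macrophage markers were higher at d35 in 7 of 19 cases, also 7 adjusted over the list alone (camera adjusted p = 0.000224, and adjusted p = 0.358 with an estimated correlation). Krt8 and Krt18 rose by 3.56 each while Epcam fell by 0.82. T and NK markers had Il7r up (camera adjusted p = 0.0341, and adjusted p = 0.358 with an estimated correlation). The T and NK call was lost without d15 replicate A (0.0861) or d35 replicate 3 (0.0773). Endothelial markers, immediate-early genes, mitochondrially encoded mRNAs and ribosomal protein genes were lower as lists. Camera adjusted p was 0.0384, 0.00475, 0.0341 and 0.0228, and adjusted p = 0.544, 0.544, 0.544 and 0.758 with an estimated correlation, with Jun the only member to pass, over all genes or adjusted over the list alone. The endothelial call was lost without d15 replicate B (0.430), d35 replicate 1 (0.0613) or d35 replicate 3 (0.123) and after length correction (0.0688). The ribosomal call was lost without d15 replicate B (0.2105), d35 replicate 1 (0.0613) or d35 replicate 2 (0.541). The mitochondrial call ended without d15 replicate B (0.0867) or d35 replicate 2 (0.182), and the immediate-early call without d35 replicate 1 (0.153). Lists without a call were MHC class II, NF-kB targets, cholesterol biosynthesis, fatty acid oxidation, oxidative phosphorylation and apoptotic uptake (camera adjusted p = 0.409, 0.133, 0.0684, 0.100, 0.302 and 0.0712). Neutrophil, dendritic, B cell, epithelial and fibroblast markers had none either (camera adjusted p = 0.0555, 0.631, 0.717, 0.443 and 0.419). The epithelial list median of -0.024 and mean of 0.312 differed in sign. Within these, Mfge8 rose by 2.77 (adjusted p = 0.00273) and Il1b from 28.5 ± 12.1 to 160 ± 69.3 (adjusted p = 0.0144). The calls of Krt18 and Il7r were lost by limma-voom. The Il1b call and that of Jun ended without d15 replicate B, those of Il7r and Epcam without d15 replicate A or B, and that of Epcam also without d35 replicate 1 or any naive replicate.

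Changes at d15 and d35 overlapped in part. Of the genes higher at d15, 125 were also higher at d35, against 26.3 for independent lists, and 94 were lower at both times, against 14.3. Cyp2ab1 and Tmem154, 2 genes, were higher at d15 and lower at d35, against 16.9 for independent lists, and 8 were lower at d15 and higher at d35, against 22.3. The log2 fold changes correlated at r = 0.424 across genes, which are not independent replicates. Simulated libraries without group differences, all 8 redrawn around the naive means, gave 0.446 (range 0.410 to 0.489 over 100 draws). Each gene was drawn independently, so the simulation carries no variation shared across genes, such as the length trend seen at both times. The covariance was 0.0578 against 0.0115 simulated, a difference of 0.0464. Signs matched for 70.4% of genes, against 64.7% simulated, and 219 genes were called with the same sign, against a simulated mean of 0.03. The correlation lay within the simulated range. The naive libraries were not split between the comparisons, in the data or in the simulation. The simulated values thus already include the effect of shared controls for genes that vary independently. Part of the excess in covariance, signs and shared calls may still come from variation shared across genes, also in the shared naive libraries. These overlaps rest on the d15 calls, which numbered 12 without d15 replicate B, 64 without naive replicate 2, 90 without d15 replicate A, 110 without naive replicate 3, 232 without naive replicate 1 and 1079 without d35 replicate 3.

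The authors' deposited table of the d15 comparison lists 10778 genes, all tested here. Of these, 389 have an adjusted p under 0.05, 180 with a positive and 209 with a negative fold change. The authors' deposited table gives Nr1d1 a log2 fold change of 3.18 (adjusted p = 2.56e-18), Tef 2.97, Fkbp5 2.63 and Mfsd6 -1.74. Among rule-named genes it also calls Siglecf (adjusted p = 0.00784), Gbp3 (0.0155) and Il1b (0.0338), which limma did not. It does not call Ifih1 (0.238), Eci1 (0.524), Bnip3 (0.19), Cox6c (0.0947), Atp5e (0.192) and Elmo1 (0.0977), which limma did. Across its genes the fold changes correlated with those of limma at r = 0.979. Both come from the same libraries, and genes are not independent replicates. Of the 389 calls in the authors' deposited table, 229 were also made by limma, all with the same sign. Of the 389, 366 were made by DESeq2 on recovered reads, 355 when only naive and d15 libraries were fitted, 196 by edgeR on all libraries, and 12 by limma without d15 replicate B.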

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

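Tests of the clock, glucocorticoid and other-cell explanations and the length-corrected fit were chosen after the results were seen. A test of the difference between the times, which share the naive reference, marked 833 genes and 17 gene lists, of which none passed with an estimated correlation and 4 passed with fry. Among single genes the log2 change from d15 to d35 was 4.99 for Mmp12, 4.33 for Fam20c, 4.14 for Clu, 3.93 for Pla2g7, 3.46 for C1qb and 3.10 for Sema4d. It was -2.70 for Nr1d1, -2.64 for Fkbp5, -2.62 for Tef, -2.11 for Nr1d2, -1.78 for Per2 and -1.76 for Cldn1. The count of 833 was 193 without d15 replicate B, 312 without d15 replicate A and 1052 without d35 replicate 2, and the Per2 call ended without d15 replicate B. Of the 10 splits of the 6 naive and d35 libraries into groups of 3, the real 1 gave 1824 genes and the highest other split 2. With 10 splits the share is never under 0.1.

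Clock genes and Fkbp5 were among the largest rises at d15. A list of clock genes driven by E-box and D-box activators was made after Nr1d1, Nr1d2, Tef and Per2 were seen and holds them, so its 7 of 10 rises and median of 1.75, which lay 1.974 above that of clock genes of the opposite phase, describe the pattern and do not test it. Another time of day at harvest may account for this, but the labels give no harvest time and any such difference coincides with the group, so it cannot be told apart from an effect of the tumor. Glucocorticoid exposure is also open, as 14 glucocorticoid receptor targets without Per1, but with Fkbp5, which prompted the list, had a median of 0.292, at percentile 100 of 10000 random lists matched on expression (central 95% of random medians -0.178 to 0.13), yet only Fkbp5 and Klf9 passed the test. The calls of Nr1d1, Nr1d2, Tef, Dbp, Fkbp5 and Klf9 held in every setting, whereas that of Per2 was lost without d15 replicate B, and those of Cry2 and Per3 without several libraries including d15 replicate B and naive replicate 2.

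Genes typical of other cells rose at d35, chiefly C1qa, C1qb and C1qc among markers of recruited or interstitial macrophages and Krt8 and Krt18 among epithelial and tumor markers. Recruited macrophages in the sort may contribute. Of the 19 list members 8 rose and 1 fell at d35, with a median of 0.1283 and a mean of 0.9575. Cd14 (596 against 531, limma adjusted p = 0.550) did not pass. Neither recruited macrophages nor induction in resident cells was excluded. Tumor or epithelial cells in the sort could bring keratins. The median of the 16 list members was 0.03792 and their mean 0.4034. Epcam fell and surfactant gene Sftpc was at 14.9 against 26.0 (limma adjusted p = 0.304). Epcam (201 scaled CPM) and Cd14 were already high in naive libraries, so their levels at d35 say little about added cells. Which of these genes KP cells express was not tested here. Endothelial and B cell markers fell at the same time. Added cells of a single other type need not raise these markers, so their fall does not decide between the explanations.

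Short transcripts were higher as a class at both times, and 8 and 5 of 22 ribosomal protein genes and 3 and 14 of 22 oxidative phosphorylation genes rose at d15 and d35, with list adjusted p = 0.741, 0.543, 0.741 and 0.387 with an estimated correlation. Against 10000 random lists matched on transcript length and expression, the ribosomal median at d15 (0.451, random median 0.229, central 95% 0.14 to 0.30) lay at percentile 100. The oxidative phosphorylation median lay at percentile 99.98 at d15 (0.368, upper limit of the central 95% 0.30) and 100 at d35 (0.441, upper limit 0.34). Random members were drawn independently and carry no correlation within a list, so these percentiles cannot decide whether length is the whole cause. Length correction ended 6 of 8 ribosomal and 3 of 3 oxidative phosphorylation calls at d15. At d35 it ended 5 of 5 and 11 of 14. The ribosomal median at d35 (0.33, random median 0.242) lay at percentile 96.57, below the upper limit of 0.338, so length may account for that rise. Per library the correlation of length with deviation from the gene mean was 0.336, 0.307 and 0.201 in naive, -0.109 and -0.18 in d15 and -0.119, 0.0137 and -0.329 in d35 libraries. RNA integrity and library chemistry were not measured in the sources used here, and a biological change in these genes stays open as untested.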

How the results depend on the processing

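Alternatives added after the data were seen were edgeR on recovered reads, pseudocounts of 0 and 3, a minimum value of 5, the block by column-name numbers and the length correction. Of these, edgeR was the main test planned at the start. For d15 against naive, 493 genes became 1455 with DESeq2, 316 with limma-voom and 1179 with only the 2 groups fitted. Leave-one-out sets gave 12 (without d15 replicate B) to 1079 (without d35 replicate 3) genes. A set with a lone d15 library assumes that it varies like the other groups. For d35 against naive, leave-one-out counts ran from 635 (without naive replicate 2) to 2294 (without d35 replicate 2). All other settings stayed within 1.5 times of 1824. The lowest of these was 1258 after length correction, of which 1063 were among the 1824. For d35 against d15, 833 became 1402 with DESeq2, 421 with only the 2 groups and 193 (without d15 replicate B) to 1052 (without d35 replicate 2) in leave-one-out sets. Genes changed in any comparison numbered 3199 with DESeq2 and 751 (without d15 replicate B) to 2427 (without d35 replicate 2) in leave-one-out sets, against 2008. The spread estimate shared by all 8 libraries assumes equal spread in the 3 groups. Correlations within a group were lowest at d35 (0.988 to 0.989, against 0.991 to 0.994 in naive libraries). Whether this difference moved the counts was not tested, nor was another cause. With a replicate block d15 calls rose to 1013 when d15 replicates A and B were set to numbers 1 and 2, and fell to 345 by the numbers of the column names. The first pairing is arbitrary for d15, whose columns could not be matched to the titles. Same-numbered naive and d35 libraries correlated at -0.00708, -0.0456 and 0.147 in their deviations, and not every library correlated best with its own number. Lists called fell from 10, 16 and 17 to 0, 0 and 0 with an estimated correlation and to 0, 10 and 4 with fry. The d15 to d35 correlation ranged from 0.376 (without d15 replicate A) to 0.463 (without naive replicate 3), and that with the authors' deposited table fell from 0.979 to between 0.908 (without d15 replicate B) and 0.953 (without naive replicate 3) when a naive or d15 library was left out. No call changed direction. Uncalled Mertk changed sign, to 0.0023 (d15) and 0.023 (d35) after length correction, and at d35 ran from -0.0803 (without d35 replicate 2) to 0.045 (without d35 replicate 3). Of values for rule-named calls, 506 of 660 stayed past the threshold at d15, 957 of 1020 at d35 and 721 of 778 between times.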

Other observations

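Opposite courses between the times were called for 140 of the 493 genes that changed at d15, so they are not particular to the 5 genes given here. All genes in this part were chosen after their values were seen. Pparg rose from 331 ± 24.7 (SD, n = 3) in naive macrophages to 514 ± 36.9 (SD, n = 2) at d15 and was at 308 ± 27.6 (SD, n = 3) at d35. Dgat2, a triglyceride synthesis enzyme, followed the same course, at 122 ± 10.5, 186 ± 12.4 and 122 ± 16.0. Lpl ran the other way, at 3853 ± 590, 2267 ± 480 and 3820 ± 101, as did Scd2, at 64.3 ± 7.4, 35.2 ± 0.01 and 71.9 ± 3.2, and the inhibitory receptor gene Lilrb4a, at 373 ± 50.5, 242 ± 3.16 and 410 ± 54.2. All 5 changed at d15 and again between d15 and d35, in opposite directions (limma adjusted p from 0.000286 to 0.0277). Both comparisons use the same d15 libraries, and no reference value for such reversals in unchanged groups was computed. The d15 changes were lost without d15 replicate B in all 5, those of Pparg, Dgat2, Lpl and Lilrb4a also without naive replicate 2, those of Dgat2, Lpl and Lilrb4a without naive replicate 3, and those of Dgat2 and Lilrb4a without d15 replicate A. Changes from d15 to d35 of Dgat2 and Lilrb4a were lost without either d15 replicate and that of Lpl without d15 replicate B.

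Added lists gave further values. Clock genes driven by E-box and D-box activators fell between d15 and d35 in 7 of 10 cases (median log2 fold change -1.62), and at d35 against naive 1 of 10 passed, Nr1d2 by 0.36 (camera adjusted p = 0.251). The Nr1d2 call at d35 was lost in 7 leave-one-out sets. Clock genes of the opposite phase had 1 of 4 lower at d15 (camera adjusted p = 0.0534). Of 15 glucocorticoid receptor targets, 2 rose at d15, Fkbp5, which prompted the list, and Klf9. The d15 camera adjusted p of 0.00202 (adjusted p = 0.184 with an estimated correlation) therefore describes the pattern and does not test it. At d35 4 rose, Klf9, Mt1, Mt2 and Il1r2 (camera adjusted p = 0.251). At d35 the Mt1 and Mt2 calls ended after length correction, and those of Klf9 and Il1r2 without any naive replicate or without d35 replicate 3. Cold-induced and heat-shock RNA-binding genes had Hsph1 up and Srsf5 down among 9 at d15 (camera adjusted p = 0.988), with both calls lost without d15 replicate A or B and that of Hsph1 also without naive replicate 2 or 3.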
